A study of Salmo salar with 8 samples.

How the data were processed

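Total RNA from single Atlantic salmon (Salmo salar) eggs was measured on single-colour Agilent arrays, 1 array per egg. Per the labels, the eggs were kept from fertilisation to 24 h in lake water (control, 4 eggs) or with road salt at 5000 mg/L (4 eggs). RNA was taken from each egg separately, so replicates are separate eggs. The labels do not say whether the eggs shared parents or an exposure vessel. The sample titles also carry the word for the eyed stage, so the stage at which the eggs were collected is not settled by the labels.

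Per the file headers, the deposited scanner files hold the green-channel intensity of each spot, with 62976 spots on each array. Per the submitters' processing notes they were made with Agilent Feature Extraction 10.7. The processed intensity in these deposited files is background-subtracted and detrended, and is not scaled between arrays. The median spot intensity and the median local background intensity were also read from the deposited files. The series' value table holds log2 values deposited by the authors for 43408 probes. How it was scaled and centred is not given in the sources used here. Its differences between arrays followed those of quantile-normalised log2 signals with a slope of 0.972 to 0.991 against control egg 2. Its column medians were -0.06, 0.02, 0.05 and 0.08 for control eggs 2, 3, 5 and 4, and 0.03, 0.01, 0.03 and 0.03 for salt eggs 3, 1, 6 and 5. The direction of the values is that of the signal, while the baseline subtracted from each probe remains unknown. The table was used only as an alternative.

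Control spots were left out, as were the 198 spots, summed over the 8 arrays, that carried a non-uniformity or population outlier flag. No probe spot was saturated. The remaining spots of a probe were averaged on the intensity scale, log2 was taken, and the 75th percentile of each array was subtracted. The arrays hold 55468 probes for 55418 target names, and 50 of these names have 2 probes, which were kept apart. A probe was tested if it was well above background on all 4 arrays of at least 1 group, which left 30942 probes (55.8%).

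Salt and control eggs were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, two-sided), with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. Every p-value and adjusted p for a probe comes from limma. Where a probe was not well above background on any array of a group, its difference is given as a lower bound. For the bound, the mean of the brighter group was set against a floored mean of the dimmer group, as normalised log2 values. On each array the floored value was the higher of the probe's own signal and the lowest signal among probes well above background. This lowest signal is not a detection limit for every probe, so folds given as "at least" are approximate. Single values per egg were compared by exact two-sided permutation tests over the 70 assignments of 4 against 4 eggs, whose smallest possible p is 0.0286. The precision is limited by the number of arrays.

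Tested on simulated data with the tested probes' own means and spreads, the limma comparison of salt against control over 30942 probes recovered 16.0% of 50 probes changed by 1 on the log2 scale. It recovered 94.0% of 50 changed by 2, 92.0% of 50 changed by 3 and 98.0% of 50 changed by 4, with 3 false calls among 153. In 20 further simulations without any change, limma made at most 1 call each. The simulated probes varied independently, with 1 SD for both groups. Real probes vary together and vary more among control eggs, so these counts do not give the false-call rate of the real data. Other splits of the real eggs into 4 and 4 gave up to 233 calls.

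Slide was read from the files: 2 slides each held 2 control and 2 salt eggs. Control eggs 2 and 3 and salt eggs 1 and 3 were on slide 1, and control eggs 4 and 5 and salt eggs 5 and 6 on slide 2. Each comparison was repeated with slide as a block and within each slide. Replicate numbers come from the labels. Numbers 3 and 5 occur in both groups, and nothing in the labels ties same-numbered eggs together.

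The files and the reference table of salmon genes used here (assembly Ssal_v3.1, 65341 genes) do not pair the arrays' target names with genes: 0 of the 55418 names matched its identifiers, symbols, synonyms or accessions. For this reason 30 gene lists written before the data were examined, including markers of the tissues an egg with an embryo holds, could not be tested, and the planned list of named genes stayed empty. By the planned ranking (largest fitted log2 difference among probes with adjusted p under 0.05 whose groups do not overlap) the first 2 probes in each direction are given by their array identifiers instead.

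The alternatives fixed before the data were examined were another background correction (normexp with an offset of 50), quantile normalisation, median centring and no scaling, no filter or a stricter filter on dim probes, flagged spots kept, slide or replicate number as a block, each slide alone, array weights, a trended and robust variance, other thresholds, the series' value table, and leaving out each egg in turn. The normexp correction was planned on mean spot intensities and was run on median spot intensities, the ones read from the files. Scaling to 6 spike-in probes, leaving out pairs of control eggs, and leaving out probes far higher in a single egg were added after seeing the data.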

Results

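Gene expression was measured in 8 single Atlantic salmon eggs, 4 kept in lake water and 4 exposed to road salt at 5000 mg/L for the 24 h after fertilisation. The study's design asks which transcripts change in eggs exposed to a high concentration of road salt. The 75th percentile of the signal of an array lay between 87.6 (control egg 5) and 167 (salt egg 6) intensity units. The share of probes well above background was 59.6% ± 3.17 (SD, n = 4) in control eggs and 60.7% ± 4.13 (SD, n = 4) in salt eggs, a difference within the spread between eggs (exact two-sided permutation p = 0.686). Within an array, duplicate spots of a tested probe differed with a median SD of 0.084 to 0.109 on the log2 scale.

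Across the tested probes, pairs of salt eggs correlated at 0.969 to 0.985 and pairs of control eggs at 0.90 to 0.966 (6 pairs each; probes are not independent replicates). Control eggs 2, 3 and 4 correlated on average more with the salt eggs (0.934, 0.964 and 0.942) than with the other control eggs (0.932, 0.952 and 0.936). Control egg 5 (0.936 with salt eggs, 0.950 with control eggs) and each salt egg correlated more with their own group. The first principal component, with 37.0% of the variance, set control eggs 4 and 5 (scores of 101 and 79.6) apart from the other 6 eggs, whose scores lay between -48.6 and -15.5. Control eggs 4 and 5 were also the 2 control eggs of slide 2. On the first component the mean score was 27.3 ± 73.9 (SD, n = 4) in control eggs and -27.3 ± 13.2 (SD, n = 4) in salt eggs (exact two-sided permutation p = 0.343). On the second component, with 31.4% of the variance, the mean score was 39.1 ± 47.0 (SD, n = 4) in control eggs and -39.1 ± 14.01 (SD, n = 4) in salt eggs (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 eggs allow). Control egg 4 lay closest to the salt eggs on this component, at -18.6 against -19.9 in salt egg 3.

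**Figure D1:**
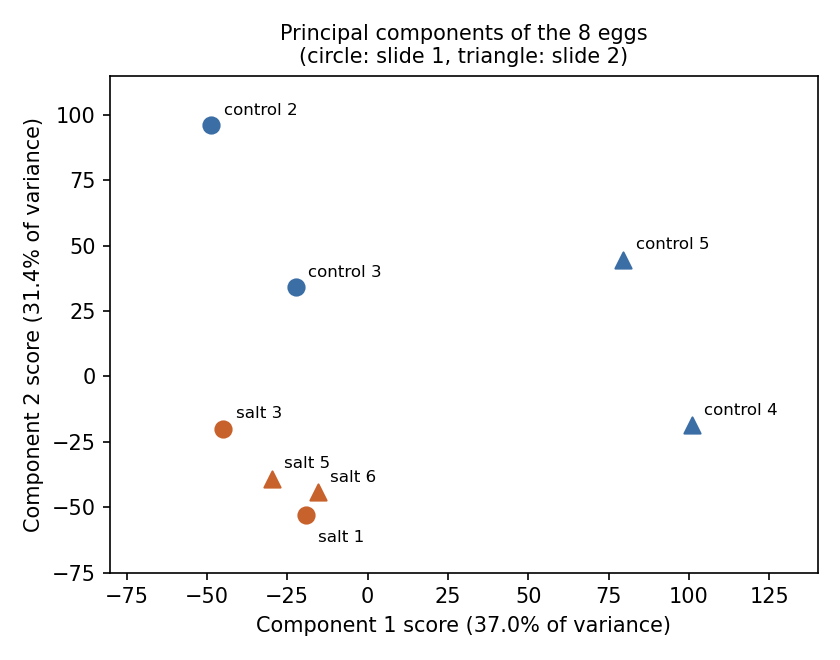
Scores of the 8 eggs on the first 2 principal components (axes, component scores from log2 signals of the tested probes; 37.0% and 31.4% of the variance), with control eggs in blue, salt eggs in orange, slide 1 as circles and slide 2 as triangles. The 4 salt eggs lie together at second-component scores of -53.1 to -19.9, while control eggs 4 and 5 lie apart on the first component.

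Among the probes that passed the test, a higher signal in salt eggs was far more frequent than a lower one. Of 30942 tested probes, 285 (0.921%) differed between salt and control eggs at an adjusted p under 0.05 in limma. Of these, 232 were higher and 53 lower in salt eggs, so that 81.4% of the differences were increases. The 2 groups did not overlap for any of the 285 probes. Over all tested probes they did not overlap for 9.89%, where chance gives 2.86% for probes chosen without regard to group. The filter on dim probes used the groups and can favour separation, so these 2 shares are not on equal terms. At an unadjusted p under 0.05, 2501 probes were higher and 2582 lower, 5083 in all against 1547 expected by chance. The excess of increases thus holds for the probes past the adjusted threshold and not for this wider set. Slide, fitted beside group in limma, gave 3994 probes at an unadjusted p under 0.05, so a count far above 1547 is not particular to salt.

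The increases began from low signals. Their median difference was 2.14 on the log2 scale (4.41-fold), with a range of 0.91 to 4.78 as fitted over the 232 probes. With the probes that have only a lower bound placed at that bound, the median was 2.07 (4.19-fold) and 122 probes exceeded 4-fold. With the normexp background correction, whose offset of 50 is added to every signal and narrows differences between dim ones, the median of the same 232 probes was 0.87. The control level of these probes had a median percentile of 5.38 among the tested probes, and their salt level one of 50.3. All 232 were well above background on the 4 salt arrays. In control eggs, 100 of them were well above background on all 4 arrays and 28 on none. These 28 probes were at least 2.50-fold to at least 18.5-fold higher in salt eggs, with a median bound of 3.82-fold. Of the 232 increases, 21 (9.05%) also differed by more than 2 (log2) between the mean of control eggs 4 and 5 and that of control eggs 2 and 3. So did 2.17% of all tested probes and 0 of the 53 decreases.

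The decreases were smaller. The 53 probes lower in salt eggs had a median difference of -1.15 on the log2 scale (2.22-fold lower), both as fitted and with bounds in place, and a range of -4.09 to -0.76; 3 of them exceeded 4-fold. With the normexp correction their median was -0.38. The control level of these probes had a median percentile of 23.1 among the tested probes, and their salt level one of 4.25. Increases and decreases alike thus lay at low signals in their dimmer group. They were well above background on the 4 control arrays. In salt eggs, 27 of them were well above background on all 4 arrays and 11 on none, and these 11 were at least 1.98-fold to at least 2.94-fold lower.

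**Figure D2:**
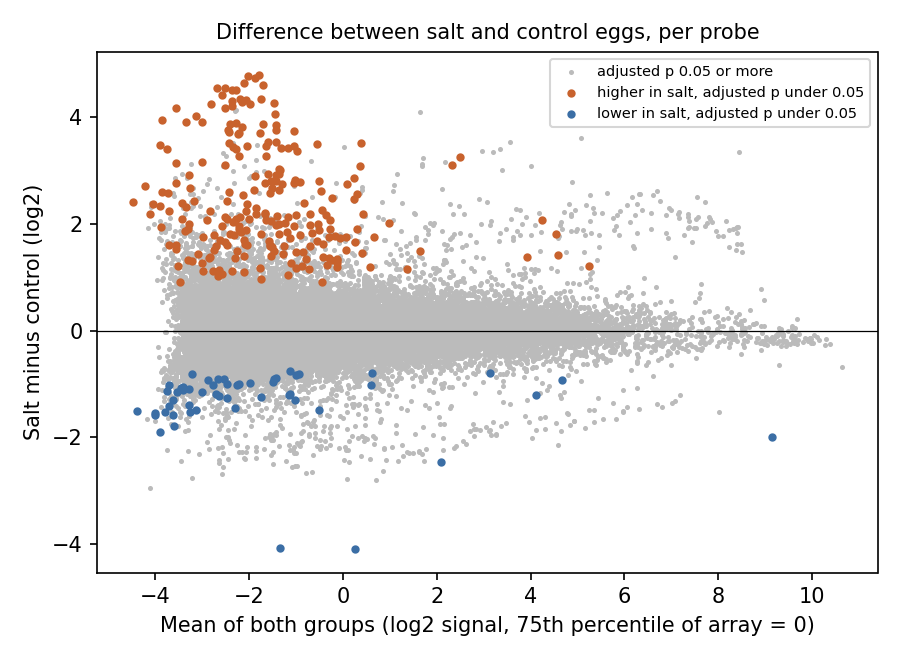
Difference between the group means (salt minus control, log2) against the mean of both groups (log2 signal with each array's 75th percentile set to 0) for the 30942 tested probes, 1 point per probe. The 232 probes higher in salt eggs (orange) reach 4.78 and lie mostly at low mean signals, and the 53 probes lower in salt eggs (blue) reach -4.09; grey probes have an adjusted p of 0.05 or more.

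Probe CUST_31447 ranked first among the increases by its fitted difference, a rank that rests in part on control signals not well above background. Its level, relative to the array's 75th percentile, was -4.17 ± 1.82 (log2, SD, n = 4) in control eggs and 0.61 ± 0.51 (log2, SD, n = 4) in salt eggs, a difference of 4.78 with an SE of 0.76 (limma adjusted p = 0.0244). It was well above background in 2 of the 4 control eggs. Probe CUST_3548 ranked next on the same terms, with -4.41 ± 1.66 in control eggs and 0.35 ± 0.48 in salt eggs (log2, SD, n = 4 each), a difference of 4.76 with an SE of 0.69 (limma adjusted p = 0.0181), and was likewise well above background in 2 control eggs. Both probes were also spread among the controls: CUST_31447 read -2.23 and -3.03 in control eggs 2 and 3, against -6.01 and -5.41 in control eggs 4 and 5. On slide 1 the difference was 3.37 for CUST_31447 and 3.68 for CUST_3548. On slide 2 neither control egg was well above background, and CUST_31447 was at least 28.4-fold and CUST_3548 at least 22.7-fold higher in the salt eggs. With the normexp correction the differences were 1.75 for CUST_31447 and 1.65 for CUST_3548, both still past the threshold (limma adjusted p = 0.0126 and 0.0128).

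Probe CUST_17704 ranked first among the decreases by its fitted difference. Its level was 2.31 ± 0.94 in control eggs and -1.77 ± 0.57 in salt eggs (log2, SD, n = 4 each), a difference of -4.09 with an SE of 0.45 (limma adjusted p = 0.0111). It was well above background in all 8 eggs. Probe CUST_31750 fell from 0.70 ± 0.93 in control eggs to -3.37 ± 1.09 in salt eggs (log2, SD, n = 4 each), a difference of -4.07 with an SE of 0.58 (limma adjusted p = 0.0176), and was well above background in 2 of the 4 salt eggs. Within slides, the difference of CUST_17704 was -4.57 on slide 1 and -3.61 on slide 2, and that of CUST_31750 was -4.55 and -3.59. With the normexp correction the differences were -2.80 for CUST_17704 and -1.74 for CUST_31750 (limma adjusted p = 0.0142 and 0.0434). The files do not pair these probes with genes, so that the genes behind the 285 differences are not named and no gene list was tested.

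**Figure D3:**
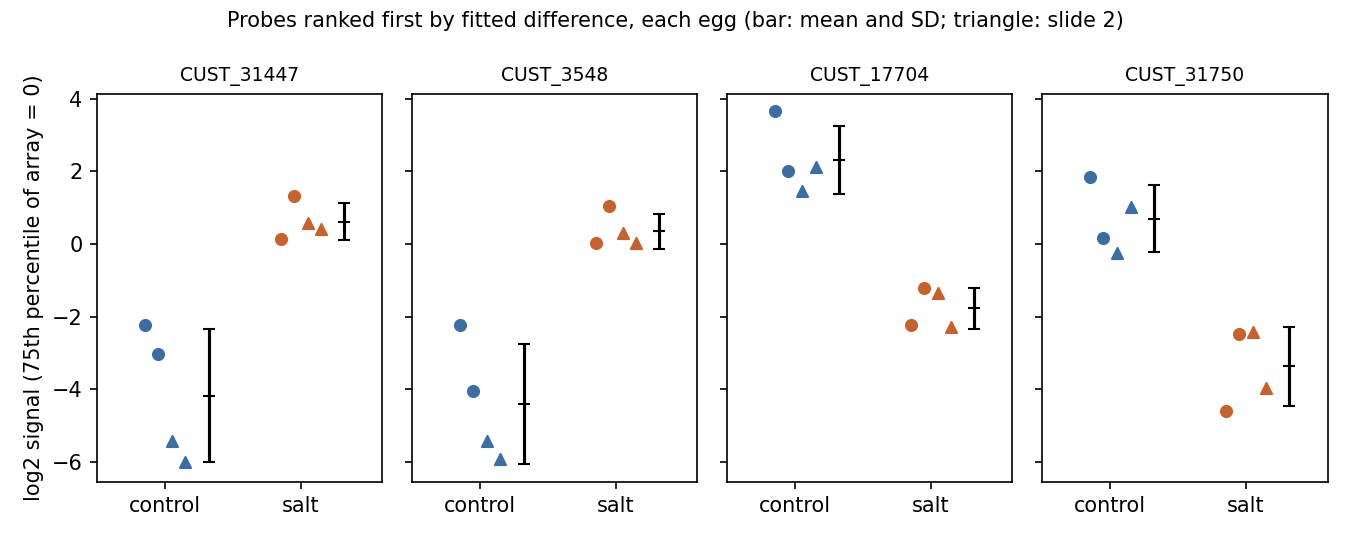
Level of the 2 probes ranked first among the increases (CUST_31447, CUST_3548) and the 2 ranked first among the decreases (CUST_17704, CUST_31750) by fitted difference, in log2 signal with each array's 75th percentile set to 0 (vertical axis), for each control egg (blue) and salt egg (orange), slide 2 as triangles, with bars for the mean and SD of 4 eggs. The 4 salt eggs lie above all control eggs for the first pair, by 4.78 and 4.76 on average, and below them for the second pair, by means of -4.09 and -4.07.

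The count of differing probes rested on few eggs. Leaving out any single egg moved it by more than 1.5 times: to 454 without control egg 2, 185 without control egg 3, 460 without control egg 4, 25 without control egg 5, 36 without salt egg 1, 152 without salt egg 3, 141 without salt egg 5 and 1 without salt egg 6. The balance of directions moved with the control eggs as well. Without control egg 4 the increases numbered 238 while the decreases rose from 53 to 222, and without control eggs 4 and 5, 118 probes were higher and 177 lower. Without control egg 2, 3 or 5 the share of increases was 91.4%, 86.5% or 96%. CUST_17704 was no longer past the threshold without salt egg 6 (adjusted p = 0.0648). CUST_31750 was no longer past it without salt egg 6 (0.0680) or control egg 5 (0.0544). CUST_3548 was no longer past it without salt egg 6 (0.0751), salt egg 1 (0.0735) or control egg 5 (0.0628). CUST_31447 was no longer past it without salt egg 6 (0.0896), 1 (0.0983), 3 (0.0539) or 5 (0.0557), or control egg 5 (0.0780). None of the 4 probes passed within slide 1 alone or with the replicate number as a block. CUST_31447 also missed the threshold with a trended and robust variance (0.0637), and CUST_31750 within slide 2 alone (0.0797). Where these calls were lost the differences stayed large, as is likely for probes chosen by their fitted size. With the replicate block they were 4.49 for CUST_31447, 4.77 for CUST_3548, -4.01 for CUST_17704 and -4.25 for CUST_31750. Without salt egg 6 they were 4.80, 4.78, -4.23 and -4.38. In all, CUST_31447 missed it in 8 of 25 alternatives, CUST_3548 in 5 of 25, CUST_17704 in 3 of 26 and CUST_31750 in 5 of 25. Over these alternatives the fitted differences ranged from 1.75 to 6.32 for CUST_31447, from 1.65 to 6.03 for CUST_3548, from -4.61 to -2.80 for CUST_17704 and from -4.55 to -1.74 for CUST_31750. The highest values of the first 2 probes are against control eggs 4 and 5 alone, in which neither was well above background. The adjusted p-values in limma ranged from 5.81e-18 to 0.148 for CUST_31447, from 5.81e-18 to 0.119 for CUST_3548, from 3.73e-08 to 0.102 for CUST_17704 and from 4.69e-08 to 0.120 for CUST_31750. The lowest value of each of the 4 probes comes from spike-in scaling, which was chosen after seeing the data. Values that low from 4 against 4 eggs are not read as stronger evidence here. The next lowest adjusted p-values in limma, with no scaling, were 1.38e-04, 7.27e-05, 6.89e-05 and 2.25e-04. In the main comparison they were 0.0244, 0.0181, 0.0111 and 0.0176.

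Both slides held 2 eggs of each group. With slide as a block, limma found 317 probes past the threshold, 259 higher and 58 lower in salt eggs. Slide itself, fitted beside group, passed the adjusted threshold for 21 probes in limma (3994 at an unadjusted p under 0.05). Within slide 1 alone it found 0 (4036 at an unadjusted p under 0.05), and within slide 2 alone 376 (3907 at an unadjusted p under 0.05), of which 364 were higher. For the 285 probes the direction could not differ between slides, since their groups do not overlap. The median difference, as fitted, was 1.89 on slide 1 and 2.44 on slide 2 for the 232 increases, and -1.15 and -1.12 for the 53 decreases. A test of whether the difference between groups itself differed between slides passed the adjusted threshold for 0 probes in limma (2598 at an unadjusted p under 0.05). Over all tested probes, the differences on the 2 slides correlated at 0.292 and had the same sign for 57.3% (probes are not independent replicates).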

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

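Each of 14 measures per array and the 4 probes given by identifier was checked, in each group of 4 eggs, for a single egg far from the other 3 by Dixon's test; the measures of probes far from all other eggs were chosen after seeing the data. Of these 36 sets, 5 held such an egg, where chance gives about 1 in 20. The median SD of duplicate spots was 0.095 in control egg 3, against 0.108 to 0.109 in the other control eggs, and 0.084 in salt egg 6, against 0.103 to 0.104 in the other salt eggs.

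The number of probes lower in 1 egg than in every other egg by more than 4 (log2) was 16 in control egg 5, against 0 or 1 in the other control eggs. It was 1 in salt egg 3 and 0 in the other salt eggs. The number of probes higher in 1 egg than in every other egg by more than 4 was 0 in control egg 5 and 1 in each of the other control eggs, and counts this small meet the criterion through a difference of 1 probe. In all, 18 probes were far lower and 8 far higher in a single egg; with spots that carry an outlier flag kept, 39 were far higher. Of the 8, 2 have 2 spots, which lay 10.67 and 12.96 apart on the array with the high value. Over all tested probes, Dixon's test singled out an egg for 4.06% in the controls and 5.06% in the salt eggs.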

How the results depend on the processing

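Scaling to spike-in probes and leaving out pairs of control eggs or single-egg probes were chosen after seeing the data. Counts of probes past the threshold are given as all (higher, lower in salt), against 285 (232, 53). They stayed within 1.5 times in total under quantile normalisation, with flagged spots kept, with slide as a block, within slide 2 alone (376; 364, 12), with a trended and robust variance (249; 224, 25), with the series' value table, without control eggs 4 and 5 (295; 118, 177), and without single-egg probes. They were fewer with normexp (108; 100, 8), with no filter on dim probes (167; 141, 26), for probes well above background on all 8 arrays (72; 65, 7) and within slide 1 alone (0; 0, 0; 4036 at an unadjusted p under 0.05 in limma). They were more with median centring (471; 402, 69), no scaling (428; 395, 33), array weights (616; 467, 149), spike-in scaling (883; 847, 36), without control eggs 2 and 3 (1067; 908, 159), at adjusted p under 0.10 (790; 549, 241), at unadjusted p under 0.05 (5083; 2501, 2582) and with 1.5-fold added to it (3599; 1892, 1707). Looser thresholds admit more probes by construction; for the other settings the cause was not tested. A total near 285 need not hold the same probes. Of the 285, 272 were also past the threshold under quantile normalisation and 254 with slide as a block. Only 137 were past it within slide 2 alone and 98 without control eggs 4 and 5. The share of increases, 81.4%, was 92.3% with no scaling, 92.6% with normexp and 95.9% with spike-in scaling, and 49.2% at unadjusted p under 0.05. Without control egg 2, 3 or 5 it was 91.4%, 86.5% or 96%; without control egg 4 it was 51.7%, through more decreases and not fewer increases, and without control eggs 4 and 5 it was 40%. No scaling and spike-in scaling moved the median difference of all tested probes by 0.15 and 0.55 on the log2 scale. Leaving out each egg in turn gave 1 (without salt egg 6) to 460 (without control egg 4) in all, 1 to 415 higher and 0 to 222 lower. Among the 285 probes, the direction changed for 1 with flagged spots kept and for 1 with the series' value table; leaving out eggs or a slide could not change it, since the groups of these probes do not overlap. None of the 4 probes given by identifier reversed.

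With the replicate number as a block, limma found 0 probes (0, 0), and 2547 at an unadjusted p under 0.05; this fit leaves 1 residual degree of freedom. Only numbers 3 and 5 occur in both groups, and the deviations of same-numbered eggs from their group means correlated across probes at 0.223 and -0.106. The planned tests of gene lists, with their alternatives, were not run because the probes could not be matched to genes. Signal over background limits the increases: 132 of the 232 probes were not well above background in all control eggs.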

Other observations

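The weighing of slide as a source of the difference among control eggs, the test of shared variation among salt eggs and the test of spread were chosen only after those results were seen. The values for bright and name-class probes were also chosen then.

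A set of bright probes differed among eggs of the same group by far more than most probes did. They were chosen for a difference between group means of more than 1. With 4 eggs per group, this choice favours probes that vary within a group. Among the 1768 tested probes with a mean log2 signal of more than 4 above the 75th percentile, 114 were higher in salt eggs by more than 1, with a median difference of 1.94, and 4 of them passed the adjusted threshold. Of these 114, 99 are among the probes, weighed further on, that differed by more than 2 between the mean of control eggs 2 and 3 and that of control eggs 4 and 5. Their median level was 7.98 and 7.57 in control eggs 2 and 3, but 2.73 and 3.23 in control eggs 4 and 5. In salt eggs 1, 3, 5 and 6 it was 5.97, 8.38, 8.09 and 6.52. The median SD of these probes was 2.93 among control eggs and 0.99 among salt eggs. Another 41 bright probes were lower in salt eggs by more than 1, with a median of -1.50, and 2 of these passed; 27 are among those same probes. Their median was 7.96, 6.59, 4.15 and 5.85 in control eggs 2, 3, 4 and 5, and lay between 4.05 and 4.75 in the salt eggs.

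Probe names fall into classes whose meaning is not given in the sources used here. Of the 6785 tested probes with names starting in OM_UG27, 80 (1.18%) were higher in salt eggs, against 136 (0.623%) of 21814 with a number only (Fisher's exact test across probes, which are not independent, odds ratio 1.90, p = 1.21e-05). Lower signals were also more frequent in this class, at 25 (0.368%) of 6785 against 26 (0.119%) of 21814 (Fisher's exact test, odds ratio 3.10, p = 9.01e-05). Of all OM_UG27 probes 41.1% passed the filter on dim probes, against 61.1% of those with a number only. Signal level was not matched in these tests, so a difference in level between the classes could give the same result. Each of the 309 probes whose name ends in AS has a partner of the same name without that ending. In the 79 pairs with both probes tested, the salt differences correlated at 0.107. For comparison, the 30 pairs of tested probes with 1 shared name correlated at 0.974.

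The 285 probes that separate salt from control eggs are more than other groupings of these eggs gave. Of the 35 ways to split the 8 eggs into 4 and 4, 1, the real one, gave as many, which is the smallest share these splits can give, so chance can be excluded only at the limit of this design. The highest of the other splits gave 233, with control eggs 2 and 3 and salt eggs 3 and 5 against the rest, the split that follows the slides gave 45, and 26 splits gave 0. Leaving out 1 egg moved the real count between 1 and 460. With spike-in scaling the median difference of all tested probes was 0.55, and with no scaling 0.15. The increases kept a median of at least 2.13 under quantile, median and spike-in scaling and with none. The increases were chosen for their difference in the same data, so this shows only that such shifts are too small to make them. The spike-in level relative to the 75th percentile was 3.53 ± 0.78 in control and 2.99 ± 0.36 in salt eggs (log2, SD, n = 4 each; exact two-sided permutation p = 0.229). Road salt remains a candidate explanation for the separation, as a hypothesis, while parentage, vessel and stage were not tested.

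The mean of control eggs 4 and 5 differed from that of control eggs 2 and 3 by more than 2 (log2) at 670 probes, and was lower at 603. At some of them 1 egg carried the difference. CUST_11138 read 1.07, 1.37 and 1.82 in control eggs 2, 3 and 4, and -5.49 in control egg 5. An effect of the slide alone would move the salt eggs on the same slides too. Yet over the 670 probes the slide difference of the salt eggs, turned to the direction of the controls, had a median of -0.073. In the controls the median was 2.91, and the SD between salt eggs of a slide was 0.74. Under quantile normalisation 100% of the 670 probes kept a difference of more than 1. They were chosen for a difference of more than 2 in the same data, so this shows only that the choice of scaling does not remove it. Salt eggs carried part of this variation too, but not at every probe of the set. CUST_12001 read 1.44, 5.30, 5.40 and 2.43 in salt eggs 1, 3, 5 and 6. CUST_13445 read 6.64, 4.96, 2.19 and 3.58 in control eggs 2, 3, 4 and 5, and 2.36 to 2.97 in the salt eggs. How much of the set the shared variation accounts for remains open. Over the 4 salt eggs the 603 probes had a mean pairwise correlation of 0.266. This was above the highest of 1000 random sets of like signal level (0.029) but under the 0.5 set for a clear case. The 603 probes had a median SD of 0.642 among salt eggs, against 0.208 over all tested probes. Probes that vary more can correlate more, so a match by signal level makes the random sets a weak comparison. The median of the 603 probes was 0.66 and 0.70 in salt eggs 3 and 5, and -0.24 and 0.04 in salt eggs 1 and 6. The split with 233 probes past the threshold follows the same order, with control eggs 2 and 3 and salt eggs 3 and 5 against the rest. No biological explanation was tested, since the labels give no group within the controls, and a fault in handling these 2 control eggs was not tested either.

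The control eggs lay farther from their group mean than the salt eggs did, by a margin that another grouping of the eggs also gave. The root mean square distance over probes was 0.506 in the 4 control eggs and 0.307 in the 4 salt eggs (log2), a gap of 0.199. With the distances recomputed for each of the 35 splits of the 8 eggs, 2 splits gave a gap as large, the real one included, and the other reached 0.210 (exact two-sided permutation p = 0.0571, with 0.0286 the smallest possible). The test thus leaves the chance assignment of eggs open as a source of the gap. The SD of a probe had a median of 0.375 among control eggs and 0.208 among salt eggs. Within slides, where each SD comes from 2 eggs, the medians were 0.256 and 0.157 on slide 1, and 0.268 and 0.148 on slide 2.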
